A study of Mus musculus with 6 samples.

How the data were processed

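RNA was measured in 6 libraries of mouse neutrophils, 3 from liver and 3 from blood, from mice fed for 1 week a diet containing 3,5-diethoxycarbonyl-1,4-dihydrocollidine (DDC), a compound that injures the bile ducts. Per the labels' protocols, cells carrying Ly6G, a surface protein of mouse neutrophils, were pulled out with magnetic beads, from liver after a Percoll density gradient and from blood after lysis of red cells. The preparation therefore differed between the groups in every library. RNA was extracted with a micro-scale column kit and made into stranded total-RNA libraries with a low-input kit, which were read as paired ends, per the labels' protocols. The labels do not say whether a liver and a blood library came from the same mouse, and the numbers of the samples were used as names only.

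The deposited files hold expected counts per gene, estimated by the authors with RSEM after alignment with STAR to GRCm38, per the submitters' processing notes, which also name FastQC 0.11.5 and limma. The versions of STAR and RSEM, the filters and whether counting used strand are not given in the sources used here, so a gene and an overlapping or antisense partner cannot be told apart by these counts. Each file has 53090 rows with an Ensembl identifier and a symbol. By identifier, 98.9% of the rows matched GENCODE release 21 for mouse (GRCm38), from which biotypes and 1-based coordinates were taken. For 213 symbols there was more than 1 row. Patch scaffolds can carry copies of genes, but whether all repeated symbols come from them was not checked. The symbol was kept for the row in the reference annotation, and reads of such genes may be split between rows. In all, 187 tested rows had values identical to another tested row, and 60 of them were called. No TPM column was analysed here.

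Expected counts were rounded to whole numbers. Total counts ran from 13054673 to 17579669 per library, and 17822 to 21540 genes had at least 1 count. At that depth 3 counts correspond to 0.18 to 0.26 CPM (the usual depth-scaled count unit, here on TMM-scaled library sizes), and such floors cover counting error only, since the libraries carry no molecular identifiers in these files. All 6 libraries were kept. No pair within a group was 1 library counted again, with a chi-square per degree of freedom of 52.1 to 79.0 over genes with at least 10 counts, which does not tell separate mice from separate preparations. Nothing in the labels says that each library is a separate mouse beyond the stated n of 3, so p-values measure the spread between these samples.

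Genes were kept with filterByExpr (minimum count 10, minimum total 15), scaled with TMM factors and tested with edgeR 4.0.16 (R 4.3.3) by a robust quasi-likelihood F test of liver against blood. p-values were adjusted by the Benjamini-Hochberg method over 13458 genes, and a gene was called at an adjusted p under 0.05. Fold changes are liver minus blood on the log2 scale, with a standard error derived from the F statistic, and levels are mean CPM ± SD over 3 libraries. A total of 40 gene lists, including 12 marker lists of other cell types, were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 40 lists. Camera with an estimated correlation and fry served as checks. Members called were also counted after adjustment over the list alone, and those counts equalled the counts over all genes unless given. The lists, the tests and the alternatives planned were chosen before the data were examined. Some genes were members of several lists, such as Nr4a1, in both the monocyte and the immediate early list. Results of lists that share members are therefore not separate.

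Genes are named by a rule. It takes the 10 largest rises and the 10 largest falls among called genes with non-overlapping groups and a mean of at least 10 CPM, leaving out gene models without names, pseudogenes, receptor segments and markers of other cells. It adds up to 4 examples per list and a fixed set of neutrophil genes. In all, 147 named genes were tested. Mpo, one of the fixed set, was not, with 93 counts over the liver and 3 over the blood libraries.

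The gene test was tried on simulated data, with 5 sets of negative binomial counts drawn from the means, dispersions and library sizes of the 13458 genes. With 200 genes changed, the median log2 fold change was 1.00 for planted 2-fold and 2.07 for planted 4-fold rises. The test called 66.8% of 4-fold rises, 49.2% of 4-fold falls and 8.00% of 2-fold changes in either direction. In those sets 12.2% of calls were false, above the nominal level, with 7.50% to 16.7% per set, although 4.66% of unchanged genes had an unadjusted p under 0.05. A further 5 sets with 4000 changed genes, near the number called in the real data, were added after that result was seen. There 2.95% of calls were false, and 85.8% of 4-fold rises, 74.0% of 4-fold falls, 40.3% of 2-fold rises and 33.7% of 2-fold falls were called. For lists, a planted list of 20 genes raised 2-fold was called in all 5 sets with 200 changed genes, and 1 of 200 tests of unplanted lists was called. Those simulated genes were independent of each other, which real genes are not.

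Alternatives were DESeq2 size factors, upper-quartile scaling, TMM without the most abundant genes, no filter and a stricter filter (10 CPM in 3 libraries), the DESeq2 1.42.0 Wald test, limma-voom, a test against a 2-fold change, the sample number as a replicate block, thinning to the smallest library, leaving out markers of other cells, and leaving out each library. Added after seeing the data were the sums of rows with one symbol, leaving out liver 3 and blood 1 together, protein-coding genes only, limma on log2(CPM + 1) and log2(CPM + 0.1), and, for the lists, upper-quartile scaling and TMM without the most abundant genes.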

Results

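Neutrophils from the liver and from the blood of mice on the DDC diet were profiled to ask how cells isolated from the injured organ differed from those in blood. Whether the liver cells had left the vessels is not known from the labels. Each group had 3 libraries, with 13778681 to 17579669 counts per liver library and 13054673 to 14403803 per blood library. The first principal component held 63.4% of the variance and separated the groups.

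In the Ly6G-selected cells of liver, most tested chemokine genes and 13 of 24 cytokine and growth factor genes were higher than in those of blood, although Il1b, the most abundant of these cytokines, was not called, and several mature neutrophil transcripts were lower. Some markers of other cells were higher there too, 9 of 11 for hepatocytes, 6 of 14 for Kupffer cells and macrophages and 8 of 13 for monocytes. Icam1, an adhesion ligand, averaged 478 ± 112 CPM in liver and 23.4 ± 2.00 CPM in blood (SD, n = 3 each), a 20.4-fold difference. Cxcl2, a chemokine that attracts neutrophils, reached 4184 ± 707 CPM against 558 ± 339 CPM, and Tnf was 25.3-fold higher. The receptor Cxcr2 fell from 1803 ± 88.1 CPM in blood to 593 ± 127 CPM in liver. Vegfa, an angiogenic growth factor, was 8.45-fold higher in liver.

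Of 13458 genes tested, 2336 were called higher and 1916 lower in liver by edgeR's quasi-likelihood test, and 2103 and 1184 of these changed at least 2-fold. Without liver 3, which had the highest hepatocyte and Kupffer cell markers, and blood 1, which had the highest haemoglobin, 1631 genes were called higher and 1195 lower. Blood 1 also had the highest median of Kupffer cell and macrophage markers among the blood libraries.

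**Figure D1:**
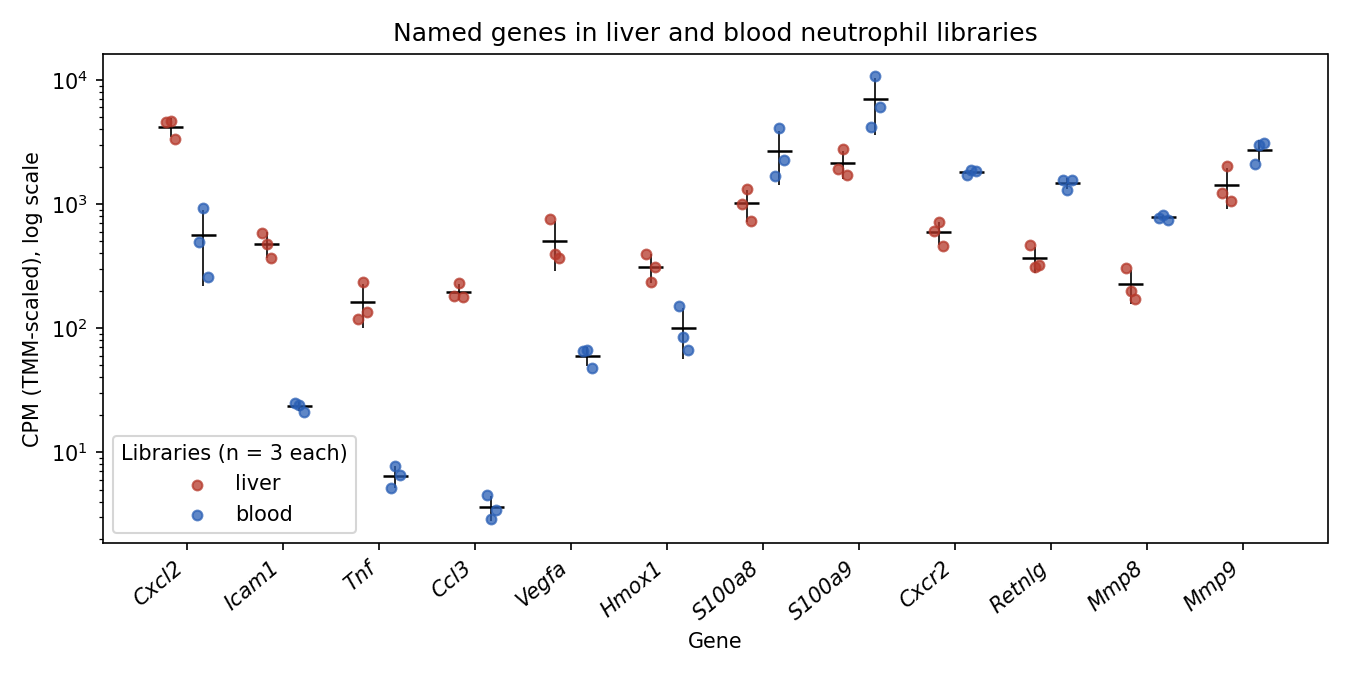
TMM-scaled CPM (log axis) of 12 named genes in each of the 3 liver and 3 blood libraries, with group means as horizontal lines and SDs as vertical lines. Every liver library lay above every blood library for Cxcl2, Icam1, Tnf, Ccl3, Vegfa and Hmox1, and below for the other 6 genes.

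The largest rises under the naming rule were led by Il23a, a subunit of interleukin 23, which lies on chromosome 10 from 128296139 to 128298752 (GRCm38). Il23a had 1107 counts over the liver libraries and 0 over the blood libraries, at least 313-fold higher against a floor of 3 counts over the group. Il1a, encoding interleukin 1 alpha, rose by 8.19 ± 0.68 on the log2 scale (SE), with an adjusted p of 0.00032, and by 9.96 without blood 1. The transcription factor genes Nr4a2, Fosl1 and Egr3 rose by 6.97 ± 0.56, 6.92 ± 0.94 and 6.09 ± 0.46, with 7.70 for Nr4a2 without blood 1 and 5.89 for Fosl1 without liver 1. Gpnmb rose 79.0-fold, Cxcl1 74.8-fold, Ccl3 54.1-fold and Hilpda, a lipid droplet protein gene, 46.6-fold, while Fam71a rose by 6.84 ± 0.54 on the log2 scale. Il1a, Nr4a2 and Fam71a had only 17, 16 and 14 counts over the blood libraries, so the sizes of their rises are uncertain. Without blood 1, Il1a was left with 0.175 and 0.0671 CPM in blood 2 and 3, under the floor of 3 counts. Single blood libraries weighed on some of these folds. The log2 fold change of Gpnmb, 6.30, became 9.44 without blood 1 and 5.69 without blood 3. That of Cxcl1, 6.22, became 7.40 without blood 2, and that of Hilpda, 5.54, became 6.56 without blood 2. In blood 1, 2 and 3, Gpnmb had 3.02, 0.175 and 0.0671 CPM. The median log2 CPM of Kupffer cell and macrophage markers took the same order there, at 3.88, -0.50 and -2.87. The largest falls included AI467606, Asb7, Cep19, Pigb, Lins1 and Fam227a, with log2 fold changes from -3.47 to -2.93, and -4.23 for Lins1 without liver 3. Nlrp12, an inhibitory receptor of the NLR family whose reads are shared with a patch copy, was 7.22-fold lower. Nrgn, Alox12 and Ctla2a were also among the 10 largest falls, and leaving out a single library ended these calls. In blood 1, 2 and 3, Nrgn had 62.6, 11.9 and 5.37 CPM, Alox12 65.2, 14.2 and 4.57 and Ctla2a 58.3, 19.2 and 7.99, in the same order as the platelet marker Itga2b, with 89.4, 26.9 and 10.5. The Nrgn call was lost without liver 1 or 2 (adjusted p 0.0750 to 0.0781), that of Alox12 without any library except blood 3 (0.0559 to 0.130), that of Ctla2a without liver 1 or 2 or blood 1 or 2 (0.0539 to 0.112), and that of Itga2b without liver 1 or 2 (0.0544 to 0.0635).

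Of 27 tested NF-kB targets and regulators, 21 rose and 0 fell, with a median log2 fold change of 2.31. The list was called higher by camera (adjusted p = 4e-24, and adjusted p = 0.12 with an estimated correlation). Traf1 was 21.8-fold higher, and Tnf, Icam1 and Il1a were among its members. Il1b, the most abundant member, had 2446 ± 182 CPM in liver and 1980 ± 712 CPM in blood, which did not pass the test (adjusted p = 0.43). Clec4f, a Kupffer cell marker, also rose, from 0.120 CPM in blood to 27.3 CPM in liver. Its log2 fold change was 6.38 without liver 3 and 7.03 without blood 3. All 5 of its blood counts lay in blood 1, so the 11.64 without blood 1 was fitted against 0 counts and measures no size. Bcl2a1b and Bcl2a1d, near-identical survival genes that can exchange reads, had log2 fold changes of 3.78 and 4.66.

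Chemokine ligands rose in 11 of 13 tested members and fell in 1, with a median of 5.01, or 4.95 with Ccl22 at its bound. The list was called by camera (adjusted p = 1.3e-14, and adjusted p = 0.090 with an estimated correlation). Ccl4 was 30.9-fold higher and Ccl2 rose by 5.70 ± 0.49, the latter with only 13 counts over the blood libraries. Ccl6 went the other way and was 2.73-fold lower. Cytokines and growth factors rose in 13 of 24 members and fell in 3, with a median of 2.14 (camera adjusted p = 2.1e-08, and adjusted p = 0.12 with an estimated correlation). Spp1, encoding osteopontin, was 27.4-fold higher, whereas Tnfsf13b was 3.07-fold lower. Osm, at 246 ± 50.7 CPM and 265 ± 145 CPM, did not pass the test.

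N1-associated genes, linked to pro-inflammatory neutrophils, rose in 7 of 10 members with 0 lower (camera adjusted p = 6.1e-10, and adjusted p = 0.12 with an estimated correlation). That list shares Tnf, Il1b and Icam1 with the NF-kB list and Ccl3 and Cxcl10 with the chemokine ligands. It also shares Cd86 and Cd80 with MHC class II, so these results are not separate. N2-associated genes rose in 5 of 13 members and fell in 1, or 6 and 1 adjusted over the list alone (camera adjusted p = 6.2e-05, and adjusted p = 0.12 with an estimated correlation). Cd274, encoding PD-L1, was 6.75-fold higher. Both sets were therefore called in the same direction. Pattern recognition and inflammasome genes rose in 7 of 20 members and fell in 1, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.022, and adjusted p = 0.45 with an estimated correlation). Tlr9 was 9.02-fold and Nlrp3 3.41-fold higher. Without blood 1 or blood 3 that list's adjusted p was 0.073 or 0.078.

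Mature neutrophil identity genes fell in 14 of 20 members and rose in 2, with a median of -1.04 (camera adjusted p = 3.3e-05, and adjusted p = 0.45 with an estimated correlation). Retnlg was 4.03-fold lower, Mmp8, a collagenase, 3.46-fold lower and Ly6g, the marker used for the isolation, 3.59-fold lower, at 8.39 ± 3.70 CPM against 30.2 ± 13.4 CPM. S100a9 and S100a8 had log2 fold changes of -1.70 and -1.39. The S100a8 call was lost without liver 1 or without liver 3 (adjusted p 0.0535 to 0.0585). Il1r2, the decoy receptor for interleukin 1, rose by 1.76 ± 0.28. Itgam, encoding CD11b, had a log2 fold change of -0.51 and did not pass the test, although it was called lower with a replicate block (adjusted p = 0.030, with 0.030 to 0.99997 over 22 alternatives). Granule proteins of immature neutrophils showed 2 higher and 3 lower of 14 members, and the list was not called (adjusted p = 0.42), with a median of 0.43, a mean of 0.05 and a downward camera direction. Mpo, Elane, Ctsg, Ms4a3 and Fcnb of that list had too few counts to be tested, so the result does not cover them. Anxa1 was 4.01-fold lower and Cd63 2.80-fold higher. Ltf and Camp, with log2 fold changes of 0.61 ± 0.69 and 1.03 ± 1.10, had negative values without liver 1 (-0.33 and -1.08).

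**Figure D2:**
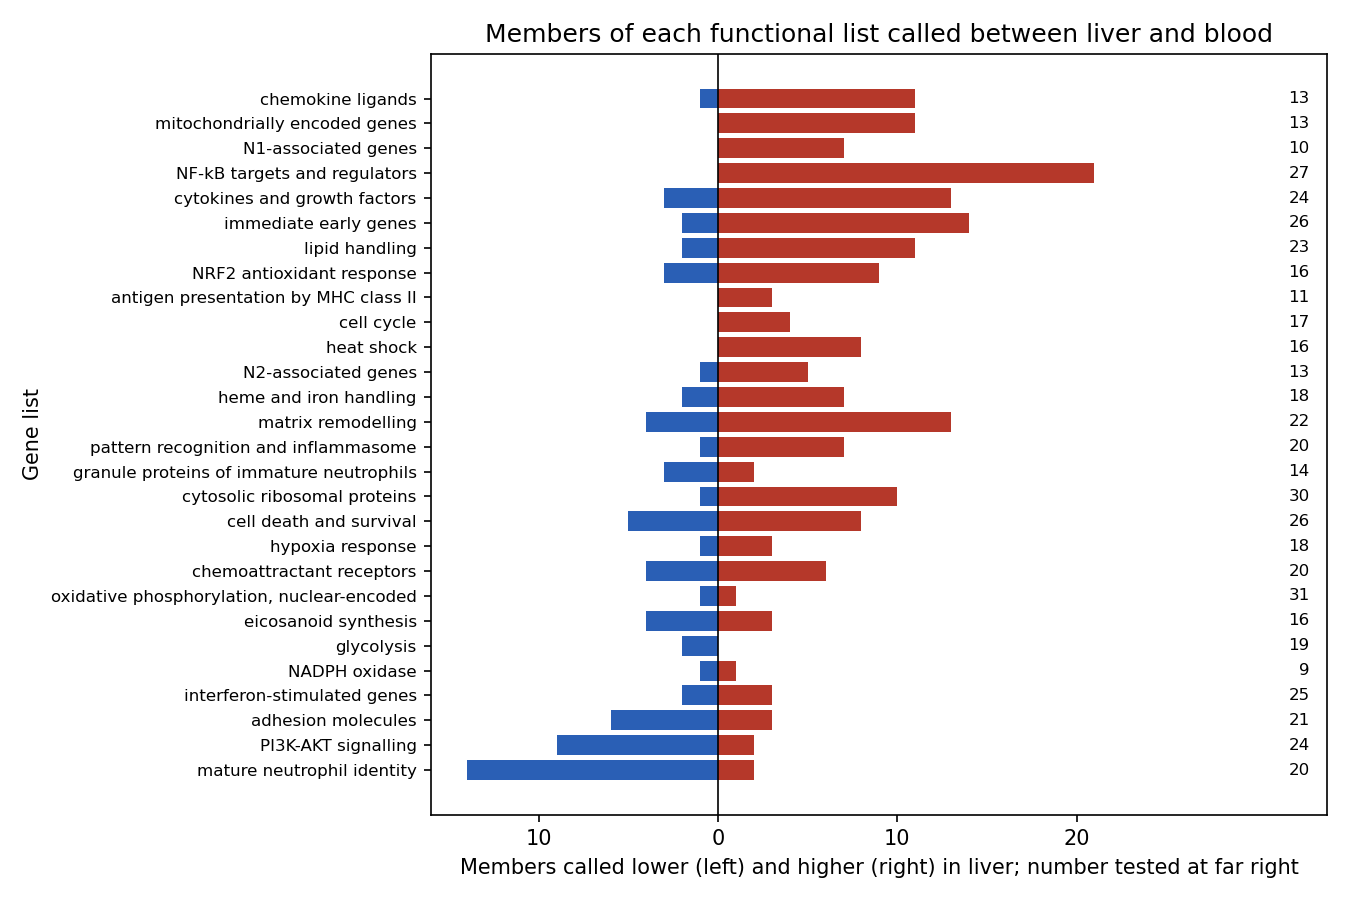
Number of tested members called lower (bars to the left) and higher (bars to the right) in liver for 28 functional gene lists, ordered by median log2 fold change, with the number tested at the far right. The NF-kB list had 21 higher and 0 lower, and the mature neutrophil list 2 higher and 14 lower.

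Immediate early genes rose in 14 of 26 members and fell in 2, or 14 and 4 adjusted over the list alone (camera adjusted p = 5.6e-08, and adjusted p = 0.45 with an estimated correlation). Dusp2, a phosphatase gene, was 14.9-fold higher. Fos went the other way, from 3016 ± 1536 CPM in blood to 1149 ± 396 CPM in liver, and its call was lost when any library except blood 3 was left out (adjusted p 0.0585 to 0.0920). Heat shock genes rose in 8 of 16 members with 0 lower, or 11 adjusted over the list alone (camera adjusted p = 0.0060, and adjusted p = 0.60 with an estimated correlation). Hspa5, an endoplasmic reticulum chaperone, was 2.30-fold higher.

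NRF2 antioxidant response genes rose in 9 of 16 members and fell in 3, with a median of 1.63 (camera adjusted p = 0.0018, and adjusted p = 0.45 with an estimated correlation). Gclc, needed for glutathione synthesis, was 4.89-fold higher, and Gsr, glutathione reductase, 1.99-fold lower. Heme and iron handling showed 7 higher and 2 lower of 18 members, or 7 and 3 adjusted over the list alone, and was not called (adjusted p = 0.17). Hmox1, heme oxygenase 1, was 3.10-fold higher and the iron exporter gene Slc40a1 2.61-fold lower. Lipid handling genes rose in 11 of 23 members and fell in 2, or 13 and 2 adjusted over the list alone (camera adjusted p = 0.00027, and adjusted p = 0.12 with an estimated correlation). Plin2, which coats lipid droplets, was 5.37-fold higher. Apoe, the most abundant member, averaged 1746 CPM in liver and 262 CPM in blood. Its call was lost without liver 1, 2 or 3 or blood 2 (adjusted p 0.0683 to 0.105). In blood 1, 2 and 3, Apoe had 583, 110 and 93.8 CPM, in the same order as the Kupffer cell and macrophage markers there. Matrix remodelling genes rose in 13 of 22 members and fell in 4 (camera adjusted p = 0.0018, and adjusted p = 0.45 with an estimated correlation). Plau, the urokinase gene, rose by 6.51 ± 0.51, but had only 8 counts over the blood libraries, so the size of its rise is uncertain. Thbs1 was 10.9-fold higher and Mmp25 2.77-fold lower. Mmp9 had a log2 fold change of -0.93, and its call was lost without liver 1 or 3 or blood 2 or 3 (adjusted p 0.0869 to 0.127).

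Mitochondrially encoded genes rose in 11 of 13 members with 0 lower, with a median of 3.19 and mt-Nd4 at 1812 CPM in liver and 198 CPM in blood (camera adjusted p = 1.4e-09, and adjusted p = 0.39 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes had 1 higher and 1 lower of 31 members, or 1 and 0 adjusted over the list alone, with a median of 0.0082 (adjusted p = 0.95). Mitochondrial mRNAs took 1.04% ± 0.381 of counts in liver and 0.114% ± 0.0420 in blood (SD, n = 3), and mitochondrial ribosomal RNA 9.98% ± 1.46 and 5.27% ± 1.17. Gm26917 and Gm42418, gene models that overlap ribosomal RNA, together took 2.02% ± 0.793 of counts in liver and 0.320% ± 0.198 in blood, with each liver library above each blood library. Cytosolic ribosomal protein genes rose in 10 of 30 members and fell in 1, or 11 and 1 adjusted over the list alone (camera adjusted p = 0.043, and adjusted p = 0.70 with an estimated correlation), and that list was no longer called without liver 1, liver 3, blood 1 or blood 3 (adjusted p 0.0575 to 0.237). Cell cycle genes rose in 4 of 17 members, or 1 adjusted over the list alone, with Pcna up by 1.98 on the log2 scale (camera adjusted p = 0.022, and adjusted p = 0.53 with an estimated correlation), with an adjusted p of 0.083 without liver 1 and 0.051 without blood 3. Antigen presentation by MHC class II had 3 higher of 11 members, Cd86, Cd80 and H2-DMb1 (camera adjusted p = 0.022, adjusted p = 0.62 with an estimated correlation, and 0.056 without blood 3).

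Several lists were not called. PI3K-AKT signalling had 2 higher and 9 lower of 24 members, or 2 and 11 adjusted over the list alone (adjusted p = 0.058), and reached 0.047, 0.030 and 0.035 without liver 3, blood 1 and blood 2. Pik3cd, a catalytic subunit, was 2.39-fold lower and the adaptor gene Pik3ap1 4.82-fold higher. Cell death and survival had 8 higher and 5 lower of 26, or 8 and 6 adjusted over the list alone (adjusted p = 0.074, and 0.033 without blood 2). Chemoattractant receptors had 6 higher and 4 lower of 20, or 7 and 4 adjusted over the list alone (adjusted p = 0.37), with C3ar1 11.9-fold higher and Fpr1 2.69-fold lower. Cxcr4 had a log2 fold change of 0.57 and an adjusted p of 0.072, and was called higher in 3 of 22 alternatives (adjusted p 0.020 to 0.99997). Adhesion molecules had 3 higher and 6 lower of 21, or 4 and 7 adjusted over the list alone (adjusted p = 0.56), with Selplg 2.68-fold lower. Glycolysis had 0 higher and 2 lower of 19 (adjusted p = 0.35), with Gpi1 2.77-fold lower. The hypoxia response had 3 higher and 1 lower of 18 (adjusted p = 0.31), and Hif1a had a log2 fold change of 1.00 with an adjusted p of 0.0504. Hif1a was called higher in 12 of 22 alternatives (adjusted p 0.00021 to 0.73), among them that without blood 2 (0.0094). Interferon-stimulated genes had 3 higher and 2 lower of 25, or 2 and 1 adjusted over the list alone (adjusted p = 0.40, and 0.033 in the downward direction without blood 3). Mx1 was up by 4.09 on the log2 scale, with only 17 counts over the blood libraries. NADPH oxidase had 1 higher and 1 lower of 9 (adjusted p = 0.69). Eicosanoid synthesis had 3 higher and 4 lower of 16 (adjusted p = 0.84), with a median of -0.02 and a mean of 0.15, and Alox5 was 2.10-fold lower.

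Markers of other cells moved with the groups as well. Hepatocyte markers rose in 9 of 11 members and fell in 1 (camera adjusted p = 0.0036, and adjusted p = 0.50 with an estimated correlation). Hpx rose by 6.20 on the log2 scale, with only 5 counts over the blood libraries. Without blood 1 its value was 7.68, with 0 and 0.0671 CPM left in blood 2 and 3. Alb, chosen after its values were seen, had 7.25, 73.2 and 148 CPM in liver 1, 2 and 3. Liver endothelial markers rose in 7 of 10 and fell in 1 (camera adjusted p = 0.0027, and adjusted p = 0.45 with an estimated correlation), with Ptprb at 4.92 ± 2.99 CPM in liver. Kupffer cell and macrophage markers rose in 6 of 14 and fell in 1 (camera adjusted p = 0.024, and adjusted p = 0.65 with an estimated correlation), with Clec4f at 27.3 ± 28.7 CPM in liver, from 5.12 in liver 2 to 59.8 in liver 3. Monocyte markers rose in 8 of 13 with 0 lower (camera adjusted p = 1.5e-05, and adjusted p = 0.45 with an estimated correlation), Fn1 and Nr4a1 among them. Dendritic cell markers rose in 5 of 13, or 8 adjusted over the list alone (camera adjusted p = 0.011, and adjusted p = 0.45 with an estimated correlation), Ccr9 and Siglech among them.

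Platelet markers fell in 5 of 10 members (camera adjusted p = 0.0040, and adjusted p = 0.58 with an estimated correlation), with Gp1ba 4.45-fold lower. B and plasma cell markers fell in 2 of 12 (camera adjusted p = 0.025, adjusted p = 0.70 with an estimated correlation, and 0.050 and 0.20 without liver 2 and blood 2). Erythroid markers had 0 of 9 called (adjusted p = 0.064, and 9.6e-06 in the downward direction without blood 3). Haemoglobin took 3.14%, 1.25% and 0.0386% of counts in blood 1, 2 and 3. Cholangiocyte markers had 2 higher and 2 lower of 6 (adjusted p = 0.84), with a median of -0.02 and a mean of 1.68. Stellate cell and fibroblast markers had 1 higher of 4, or 3 adjusted over the list alone (adjusted p = 0.16). T and NK cell markers had 1 higher and 1 lower of 15, or 0 adjusted over the list alone (adjusted p = 0.31, and 0.045 without liver 2). Markers of eosinophils, basophils and mast cells had 0 of 3 called (adjusted p = 0.92).

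**Figure D3:**
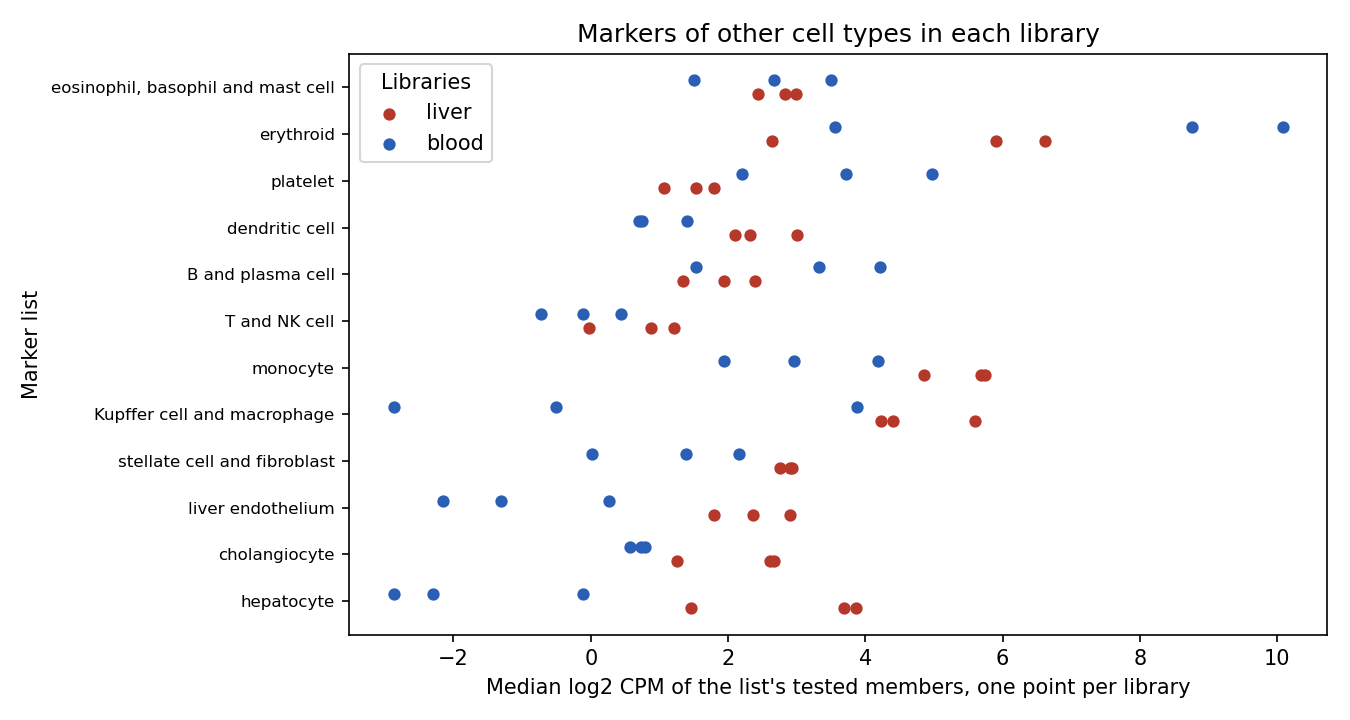
Median log2 CPM of the tested members of 12 marker lists of other cell types, 1 point per library, for 3 liver and 3 blood libraries. For Kupffer cell and macrophage markers the liver libraries lay at 4.23 to 5.60 and the blood libraries from -2.87 to 3.88.

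Over the 40 lists, camera called 20 higher and 3 lower at the preset correlation and 0 with an estimated correlation, where 6 lists had an unadjusted p under 0.05, while fry, which does not compare a list with other genes, called 21.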

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

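Each of the 22 alternatives was applied to the gene calls, and no called gene was called in the opposite direction in any of them. Called genes that lost their call were not counted there, whatever their sign. The planned fits on deposited TPM were not run. The alternatives added after seeing the data are the summed rows, the fit without liver 3 and blood 1, protein-coding genes, the fits on log2(CPM), and upper-quartile scaling and TMM without abundant genes for lists. Against 2336 higher and 1916 lower, the stricter filter gave 1427 and 1181 with 6896 genes tested and moved the median by 0.19, the 2-fold test gave 827 and 268, and without liver 3 and blood 1 the lower calls were 1195. With 1 library left out, 2795 to 3213 of the 4252 calls were kept, as fewer samples give fewer calls, and 26 of 127 called named genes lost their call at least once. Deviations of same-number libraries from their group means correlated at 0.054, 0.16 and 0.023, and those of other numbers at -0.175 to 0.120. The rule asked for over 0.1 in every same-number pair, so the numbers were not taken to pair them. These values do not exclude that same-number libraries are paired, and the main test does not allow for it. The fit with a replicate block called 2322 higher and 2312 lower. Under that block, cell death reached 0.020 and erythroid markers 0.00034, and B cells 0.082.

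With an estimated correlation, lists called numbered 0 higher and 0 lower, with adjusted p of 0.090 for chemokines, 0.12 for NF-kB, cytokines, N1, N2 and lipid handling, 0.39 for mitochondrial genes, 0.45 for neutrophil identity, immediate early, NRF2, matrix, pattern recognition, endothelium, monocyte and dendritic lists, 0.50 for hepatocytes, 0.53 for cell cycle, 0.58 for platelets, 0.60 for heat shock, 0.62 for MHC class II, 0.65 for Kupffer cells and 0.70 for ribosomal proteins and B cells (0.698). For N2 (-0.027) and lipid handling (0.0093) the estimated correlation lay below the preset 0.01, so a higher correlation did not end those calls. A call lost in this check is therefore not in itself a sign of correlated members. Fry ended the calls of MHC class II (0.081), ribosomal proteins (0.099), heat shock (0.066), B cells (0.30), Kupffer cells (0.076) and platelets (0.13), and called PI3K-AKT (0.0155), stellate cells (0.0155), cell death (0.045) and iron handling (0.036), while eicosanoid synthesis turned sign (0.856). The stricter filter left 1 list lower, and gave 0.088 for cell cycle and dendritic cells, 0.039 for cell death, 0.865 for B cells and hepatocytes (the latter with its sign turned), 0.24 for Kupffer cells, 0.33 for endothelium and 0.079 for platelets. There NADPH oxidase (0.929) and adhesion (0.884) also turned sign. Protein-coding genes alone gave 0.059 for ribosomal proteins, 0.073 for B cells and 0.981 for nuclear oxidative phosphorylation, which turned sign. Upper-quartile scaling called the erythroid list (0.040). Without liver 3 and blood 1, PI3K-AKT reached 0.046, and MHC class II (0.077), ribosomal proteins (0.076) and pattern recognition (0.061) were lost, with turned signs for cholangiocytes (0.99994) and nuclear oxidative phosphorylation (0.964). The cause was not tested.

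Leaving out each library, lists called lower numbered 2 to 5, and adjusted p ranged over 0.058 to 0.858 for glycolysis, 0.759 to 0.966 for nuclear oxidative phosphorylation, 0.033 to 0.899 for interferon-stimulated genes, 0.033 to 0.298 for cell death, 0.030 to 0.083 for PI3K-AKT, 0.0094 to 0.083 for cell cycle, 0.00033 to 0.056 for MHC class II, 0.0042 to 0.078 for pattern recognition, 0.00995 to 0.237 for ribosomal proteins, 0.425 to 0.989 for cholangiocytes, 0.045 to 0.577 for T and NK cells, 1.4e-06 to 0.203 for B cells, 9.6e-06 to 0.167 for erythroid markers and 0.344 to 0.954 for eosinophils, basophils and mast cells.

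Of the uncalled named genes, 9 gained a call in at least 1 alternative, Hif1a in 12, Cxcr4 in 3 and Itgam in 1. Other uncalled genes turned sign. Cd44 gave 0.036 with upper-quartile scaling, 0.13 with the stricter filter and 0.039 without liver 3 and blood 1, and Atp5b gave 0.0073, 0.10 and 0.12 there. Under the stricter filter Wdfy4 gave 0.025 and Osm 0.078, and Osm gave 0.046 with voom, 0.049 with the block, 0.0456 on log2(CPM + 1) and 0.0465 on log2(CPM + 0.1). Leaving out each library, Ltf and Camp, at 0.61 and 1.03, turned sign without liver 1, and the ranges were -0.21 to 0.097 for Cd44, -0.63 to 0.13 for Pkm, -0.23 to 0.019 for Atp5b, -0.52 to 0.32 for Osm, -0.33 to 1.26 for Ltf and -1.08 to 1.61 for Camp.

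Thinning to the smallest library kept 4134 of the 4209 calls whose genes were still tested, and lower depths were not tried. Depth bounds the fold of Il23a, with 0 counts in blood, at 313 or more.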

Other observations

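All tests of explanations below were chosen after the patterns were seen, except the counts over other splits. Among genes in none of the lists and chosen here after their values were seen, Tgm2, a transglutaminase, averaged 3473 ± 1420 CPM in liver and 205 ± 127 CPM in blood (SD), a log2 fold change of 4.08 ± 0.53. Bhlhe40, a transcription factor, rose by 4.28 ± 0.42, and the kinase gene Pim1 by 2.27 ± 0.38. The NF-kB inhibitor gene Nfkbid rose by 3.03 ± 0.22 and Irak2 by 2.69 ± 0.19. Lower in liver were the protease gene Adam19, at -2.38 ± 0.21, the glucocorticoid-induced gene Tsc22d3, at -2.14 ± 0.19, and Jaml, a junctional adhesion molecule, at -2.28 ± 0.25. Outside the lists, 886 protein-coding genes with groups apart rose at least 4-fold and 120 fell.

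The real division of the libraries called 4252 genes, and the highest of the other divisions called 0 by edgeR (at most 416 genes at an unadjusted p under 0.05), so 1 of 10 splits gave as many. For lists, 1 of 10 splits gave as many, with 23 in the real division and 20 in the highest other. With 10 splits a share under 0.05 cannot be reached, and each other split puts 2 libraries of a tissue with 1 of the other, so it keeps part of the tissue difference and does not stand for no change.

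Of 27 NF-kB genes 21 were higher in liver, and of 13 chemokine genes 11 were higher and Ccl6 lower, list calls lost with an estimated correlation (adjusted p 0.12 and 0.090), and macrophages carried through the Ly6G beads, with Clec4f at 27.3 CPM in liver, are a candidate source. Over the 3 liver libraries the median slope of those 40 genes on the Kupffer and macrophage markers was -0.21 (95% bootstrap interval over genes -0.29 to -0.031), where a slope near 1 is predicted, but without liver 3 the slope was 0.29 (0.15 to 0.44) over markers differing by 0.82 log2 units, under the 1 unit asked for, so it stays open. Monocyte markers ranged over 0.64 log2 units among liver libraries, too little for a test (slope 0.055). Activation during isolation cannot be told apart from the tissue, since the preparation differed in every library, and 14 of 26 immediate early genes were higher and 2 lower, Fos (call lost without any library except blood 3, adjusted p 0.0585 to 0.0920) and Dusp1 (lost without any except liver 1, 0.0557 to 0.144), with the list call lost at an estimated correlation (0.45). An effect of the injured liver on the cells also stays open, as untested.

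Of 13 mitochondrially encoded genes, 11 were called higher in liver, against 1 of 31 nuclear-encoded partners, and the list call was lost with an estimated correlation (adjusted p 0.39). Reads moved from nuclear copies would make those copies fall. The lowest log2 fold change of 3 such copies (Gm10222, Gm28661 and Gm29216) was 2.35. Reads of the mitochondrial genes can also be assigned to these copies, so their rise cannot decide whether reads moved, and that stays open. Hepatocytes in the sort may contribute. The slope on hepatocyte markers was 0.30 (0.24 to 0.36) over 3 liver libraries and 0.65 over liver 1 and 2 (0.44 to 0.72). These intervals resample genes and not libraries. In liver 1, 2 and 3 the median log2 CPM was 1.46, 3.69 and 3.86 for hepatocyte markers. For the mitochondrial genes it was 8.60, 9.49 and 9.03. Liver 1 was lowest for both, but liver 3 was highest only for the markers. A contribution of hepatocytes stays open. The tissue of origin stays open too, as untested.

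Of 20 mature neutrophil genes, 14 were lower in liver and 2 higher, and the list call was lost with an estimated correlation (adjusted p 0.45). A smaller share of neutrophils might give the fall if all fell alike. Their log2 fold changes ran from -2.01 to 1.76 and were more unlike than their errors allow (heterogeneity Q 254, against a 95% point of 30.1 over 20 genes), which argues against it as the whole cause. A smaller share as part of the cause, and a change within the neutrophils, stay open.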
